A study of Caenorhabditis elegans with 4 samples.

How the data were processed

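The samples were 4 ribosome profiling libraries from whole young adult worms, 2 of the N2 wild type and 2 of the cey-1(rrr12) cey-4(ok858) double mutant, and no RNA-seq libraries were analysed here, so a footprint level combines the amount of a message with its ribosome occupancy. Per the labels' protocols, worms hatched overnight were grown on plates to the young adult stage and frozen, monosomes were purified, the protected fragments were size-selected by gel, and libraries were prepared with a small RNA ligation kit and barcoded primers. The authors' deposited table held whole-number counts per gene for each library, and Bowtie is the aligner per the submitters' processing notes, with no version given. The genome build, the annotation, the counting rule for reads that match several genes or lie on either strand, and any filter on reads are not given in the sources used here. The authors also deposited log2 values, which were recomputed from the counts as log2 of the count scaled to the smallest library total plus a pseudocount of 8, within 0.0005 of the deposited values, so they are normalized by total count alone. No genome or coding lengths were used, so no coordinates are printed and the trend with coding length that had been listed as a comparison was not run.

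The table named 20182 features by WormBase identifier. Of these, 18778 matched a gene symbol in the reference name table, 3 more matched by sequence name, and 1401 had no symbol. The 3 that matched by sequence name repeat the genes pat-10, eps-8 and pmt-1, which are also present under their WormBase identifier, and these repeats were left out, leaving 20179. No sample column was left unused. The RefSeq table of the WBcel235 assembly served only for names and for which genes neighbour each other.

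Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr with a minimum count of 10, glmQLFit with robust estimation and glmQLFTest, 2-sided, with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. The 27 gene lists, the tests, the alternatives and the rule for named genes were written before the data were examined. Lists were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01, adjusted over the 27 lists, and again with the correlation estimated per list. With 4 libraries the estimated correlation leaves little power: in data simulated from these libraries, a list of genes shifted by 0.25 was found by camera at the preset correlation (adjusted p = 7.1e-25) but not with an estimated correlation (adjusted p = 0.17), and neither called any of 26 unshifted lists. Genes were drawn independently in that simulation, so it cannot show how often the preset falsely calls lists of correlated genes. In the data the estimated correlation was 0.408 for cytosolic ribosomal proteins and 0.944 for yolk proteins. The gene test was checked on simulated counts with 200 changed genes over 12901 genes: it recovered 36% of those changed 1.2-fold, 67.3% at 1.5-fold, 80% at 2-fold and 98% at 4-fold, with 8 false calls among 148 (5.4%). Far more genes passed in the data (2278 higher and 2177 lower) than were changed in that simulation. Simulated genes also followed the dispersion trend, without outlying genes, so these rates need not hold for the data. A median and a matched-abundance percentile were computed per list from 10000 random lists.

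Named genes followed a fixed rule. It took the 4 Y-box genes, then the 12 genes with the largest rise and the 12 with the largest fall among genes with an adjusted p under 0.05, a mean of at least 30 counts and both mutant libraries on the same side of both N2 libraries. It also took up to 4 members of each list, the 2 with the lowest p and the 2 with the highest mean CPM. Any other gene is said to have been chosen after its values were seen. Totals ranged from 22334239 to 32960588 counts, and 3 counts, the most a count of 0 allows, amounted to 0.091 to 0.134 CPM. The libraries of a group differed by more than counting noise (chi-square per degree of freedom 24.5 in N2 and 8.25 in the mutant, much of it from the gene K08E7.6, and 5.39 and 2.14 without that gene), so neither pair was a library deposited a second time. The biological coefficient of variation was 4.8%, and the standard deviation of log2 CPM differences for genes of 100 or more counts was 0.139 and 0.174 within groups and 0.326 to 0.367 between them.

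Alternatives were DESeq2 1.42.0 size factors and Wald test, upper-quartile factors, no low-count filter, at least 50 counts in 2 libraries, limma-voom, limma on the deposited log2 values, a test against a fold change of 1.2, a replicate block, leaving out each library in turn (1 residual degree of freedom, the lone library being assumed to vary like those of the other group), fry in place of camera, and msp and his genes left out. Centring on the somatic lists set the median log2 fold change over the 313 tested genes of the muscle, basement membrane, cuticle collagen, neuronal and intestinal lists to 0 and was added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading tables and drawing.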

Results

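Ribosome-protected fragments were sequenced from whole young adult worms of Caenorhabditis elegans, in 2 libraries of the wild-type strain N2 and 2 libraries of a double mutant carrying cey-1(rrr12) and cey-4(ok858). The Y-box proteins encoded by the cey genes bind messenger RNA through a cold-shock domain, and the series title links them to the formation of polysomes, the messages loaded with several ribosomes. The comparison addresses which messages gained or lost a share of the ribosome footprints in the absence of intact cey-1 and cey-4. Total gene counts were 32960588 and 27906409 in the N2 libraries and 27219638 and 22334239 in the mutant libraries, and 16175 to 16695 genes had at least 1 count. The yolk protein gene vit-6 was the most abundant gene in each of the 4 libraries, with 3.70% and 3.23% of the counts in N2 and 4.00% and 3.91% in the mutant. Levels are given below as normalised footprint counts (CPM, counts relative to the library total), mean ± SD of 2 libraries per group, and log2 fold changes are mutant relative to N2 with their standard error (SE).

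Footprints on both mutated genes were almost lost in the mutant. cey-4 (WBGene00000475) fell from 265 ± 2.40 to 1.70 ± 0.24 CPM, a log2 fold change of -7.27 (SE 0.075; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 9.87e-74). cey-1 (WBGene00000472) fell from 71.8 ± 2.67 to 3.99 ± 0.21 CPM, a log2 fold change of -4.17 (SE 0.081, edgeR adjusted p = 1.36e-54). The remaining cey-4 footprints amounted to 0.705% (exact Poisson 95% interval 0.525 to 0.927) and 0.577% (0.40 to 0.806) of the N2 level in the mutant libraries, from 51 and 34 counts. For cey-1 the remainder was 5.36% (4.39 to 6.49) and 5.77% (4.65 to 7.07), from 105 and 92 counts, and whether these counts lie inside or outside the altered part of either gene was not analysed here. The intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Of the germline paralogs, cey-2 (WBGene00000473) fell by 0.22 on the log2 scale (SE 0.053, edgeR adjusted p = 6.06e-04), from 1149 ± 53.0 to 987 ± 4.61 CPM. cey-3 (WBGene00000474) had 589 ± 28.3 and 550 ± 9.34 CPM and a log2 fold change of -0.10 (SE 0.043) that did not pass the test (edgeR adjusted p = 0.0671; -0.15 and 0.0337 without N2 replicate 1). Over the Y-box list, 3 of 4 members fell, 4 fell when adjusted over the list alone, and camera gave an adjusted p of 2.89e-07 (adjusted p = 0.208 with an estimated correlation). Since 2 of the 4 members are the mutated genes themselves, this list test follows from the genotype and says nothing of cey-2 and cey-3.

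**Figure D1:**
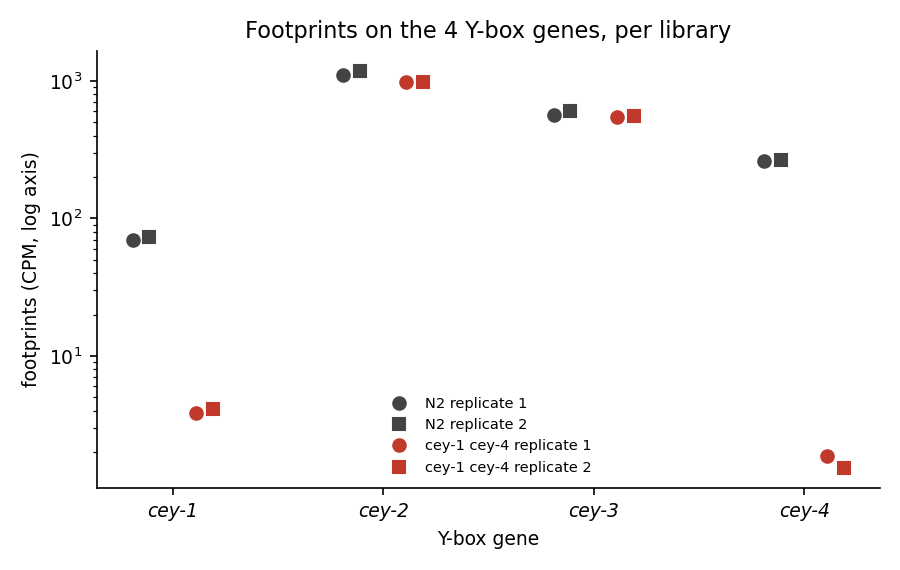
CPM of the 4 Y-box genes in each library on a log axis, N2 beside the mutant. cey-1 and cey-4 sit at 3.99 and 1.70 CPM on average in the mutant against 71.8 and 265 CPM in N2, while cey-2 and cey-3 average 987 and 550 CPM in the mutant against 1149 and 589 CPM in N2.

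Across the genome, oocyte and eggshell genes had the lowest median among the gene lists apart from the Y-box list, and sperm, muscle and basement membrane genes the highest medians. Of 13086 genes tested, 2278 rose and 2177 fell in the mutant, and 8631 did not pass the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Most changes were small: 3408 of the calls (76.5%) lay within 1.5-fold, and 239 genes rose and 118 fell by more than 2-fold. Libraries of a group resembled each other more than libraries across groups, with a Spearman correlation over genes of 0.9959 and 0.9958 within groups and 0.9873 to 0.9885 between them. Both mutant libraries lay on the same side of both N2 libraries for 64.8% of the genes tested, against 33.3% by chance.

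Of the genes with the largest falls among those with a mean of at least 30 counts, spn-4, an RNA-binding protein needed in the early embryo, fell from 15.8 ± 0.39 to 3.69 ± 0.51 CPM (log2 fold change -2.11, SE 0.112, edgeR adjusted p = 5.5e-27). The P granule components meg-1 and meg-3 fell by 1.88 (SE 0.104, edgeR adjusted p = 7.72e-26) and by 1.92 (SE 0.159, edgeR adjusted p = 5.31e-17) on the log2 scale. memi-3, a maternal regulator of meiosis, had a log2 fold change of -1.84, and marc-3 was at 0.251 of its N2 level. The others in this set were the F-box genes fbxa-192 (-2.87) and fbxa-170 (-2.13), the forkhead gene fkh-4 (-2.05), the G-protein regulator rgs-9 (-1.88) and the Skp1-related gene skr-7 (-1.84), besides cey-1 and cey-4 themselves. The genes with the largest rises under the same limit were all of low abundance, at most 5.89 CPM in the mutant. fog-3, a gene that promotes the sperm fate in the germline, rose from 0.49 ± 0.082 to 1.89 ± 0.13 CPM (log2 fold change 1.92, SE 0.301, edgeR adjusted p = 2.49e-07). ech-9, an enoyl-CoA hydratase family gene, rose from 1.2 ± 0.24 to 4.29 ± 0.11 CPM (log2 fold change 1.85, SE 0.193, edgeR adjusted p = 8.12e-13). The bestrophin genes best-11 and best-12 rose by log2 fold changes of 1.77 and 1.52, the acyltransferase gene oac-32 by 1.62 and nspc-16 by 1.89. The remaining 6, F35E2.5, F46F5.11, M05B5.3, ZK849.1, H11L12.1 and F21A3.4, rose by log2 fold changes of 1.57 to 1.78.

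**Figure D2:**
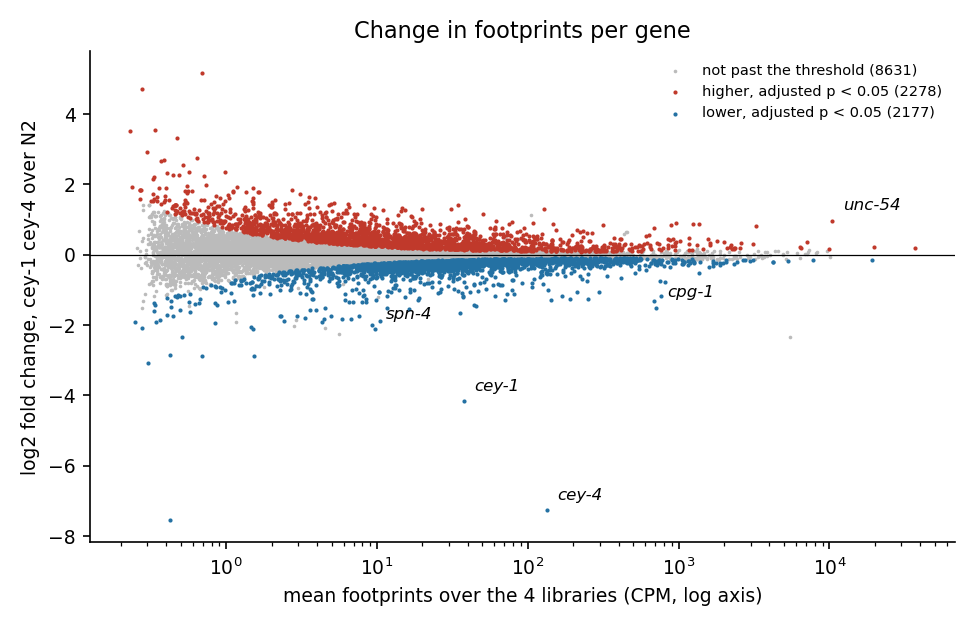
Log2 fold change of each of the 13086 genes tested (mutant relative to N2) against mean CPM on a log axis, with genes past the edgeR test in colour. cey-4 and cey-1 lie at -7.27 and -4.17, fipr-6, which had 0 counts in both mutant libraries, also lies in that range at low CPM, and spn-4, cpg-1 and unc-54 are marked among the genes discussed.

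Oocyte and sperm messages moved in opposite directions. Of 36 oocyte and eggshell genes, 30 fell, 1 rose and 5 did not pass the test, with a median log2 fold change of -0.92, and the counts were the same when adjusted over the list alone. camera put the list lower (adjusted p = 1.18e-35; adjusted p = 0.189 with an estimated correlation). The eggshell proteoglycan gene cpg-1 fell from 1053 ± 22 to 372 ± 10.1 CPM (log2 fold change -1.50, SE 0.048, edgeR adjusted p = 6.73e-40). egg-1, which encodes an oocyte surface protein needed for fertilization, fell from 204 ± 1.98 to 83.5 ± 2.92 CPM (log2 fold change -1.28, SE 0.041, edgeR adjusted p = 6.73e-40). The permeability barrier gene perm-2 fell by 0.20 (edgeR adjusted p = 0.00115; log2 fold change -0.13 and 0.0852 without N2 replicate 2), whereas perm-4 had a log2 fold change of -0.10 that did not pass (edgeR adjusted p = 0.148; log2 fold change -0.14 and 0.0237 without N2 replicate 1). The member that rose was the kinase gene mbk-2, at 0.27, chosen after its values were seen. In the same libraries the oocyte and eggshell list held 0.899% and 0.924% of all counts in N2 and 0.592% and 0.579% in the mutant.

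Of 25 major sperm protein genes, 19 rose, none fell and 6 did not pass the test, and 19 rose when adjusted over the list alone. The list median was 0.41, or 0.25 when centred on somatic genes, and camera put it higher (adjusted p = 4.37e-14; adjusted p = 0.189 with an estimated correlation). msp-33 rose from 41.5 ± 2.72 to 70.7 ± 3.67 CPM (log2 fold change 0.77, SE 0.053, edgeR adjusted p = 3.76e-20) and msp-31 by 0.53. These genes are near-identical copies, so the share of footprints each received is uncertain. The other sperm genes moved the same way: of 65, 49 rose, 3 fell and 13 did not pass. They include 26 spe genes but also name families such as ssp (12 genes) and nspd (9 genes). How alike the sequences of these 65 genes are was not examined. Their median was 0.45, or 0.29 when centred on somatic genes, with 51 rising and 3 falling when adjusted over the list alone (camera adjusted p = 4.03e-17; adjusted p = 0.189 with an estimated correlation). spch-1, which encodes a sperm chromatin protein, rose from 117 ± 1.2 to 190 ± 11.2 CPM (log2 fold change 0.70, SE 0.041, edgeR adjusted p = 3.55e-24), smz-1 by 0.64 and ssq-2 by 0.45. The 3 that fell, chosen after their values were seen, were the vesicle trafficking gene spe-39, ssp-37 and sss-1. The sperm genes together held 0.309% and 0.323% of counts in N2 and 0.415% and 0.430% in the mutant.

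Of 44 germline genes, 20 fell, 2 rose and 22 did not pass the test, with a median of -0.14, and 22 fell when adjusted over the list alone (camera adjusted p = 4.93e-06; adjusted p = 0.189 with an estimated correlation). gld-3, a poly(A) polymerase partner, fell by 0.57 (SE 0.066, edgeR adjusted p = 3.51e-11), sqv-4 by 0.43 and the germline eIF5A homologue iff-1 by 0.26. The P granule helicase gene glh-1 had a log2 fold change of 0.04 that did not pass the test (edgeR adjusted p = 0.581) and became -0.12 under the centring on somatic genes described below. The risers, chosen after their values were seen, were glh-4 and msh-5. Among 24 genes of the histone list, which was drawn up as replication-dependent but also holds replication-independent variants, 6 rose, 9 fell and 9 did not pass, and 10 fell when adjusted over the list alone. The list was not called (camera adjusted p = 0.288; adjusted p = 0.535 with an estimated correlation). his-48 fell by 0.60 (SE 0.077, edgeR adjusted p = 1.14e-09), whereas 4 of the 6 that rose, his-70, his-71, his-72 and his-74, encode H3.3 variants, which are deposited independently of replication; his-71 and this grouping were chosen after the values were seen, and the grouping was not tested. his-70 rose from 3.62 ± 0.13 to 8.84 ± 0.42 CPM. Histone genes of a class are near-identical, so their individual counts are uncertain.

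Most genes of the muscle and basement membrane lists rose. Of 49 muscle genes, 31 rose, 3 fell and 15 did not pass the test, with a median of 0.31 (0.15 when libraries were centred on somatic genes, muscle genes included) and the same counts adjusted over the list alone (camera adjusted p = 4.58e-18; adjusted p = 0.189 with an estimated correlation). The myosin heavy chain gene unc-54 rose from 7085 ± 291 to 13840 ± 5.47 CPM (log2 fold change 0.97, SE 0.054, edgeR adjusted p = 1.22e-25). The paramyosin gene unc-15 rose by 0.83 (SE 0.059), the alpha-actinin gene atn-1 by 0.84 (SE 0.037) and the ryanodine receptor gene unc-68 by 0.91 (SE 0.043), with edgeR adjusted p values of 4.45e-20, 5.05e-31 and 5.45e-30. The 3 members that fell, chosen after their values were seen, were the actin gene act-2 and the pharyngeal troponin genes tnt-4 and tnc-2. The muscle list held 2.83% and 2.96% of counts in N2 and 4.27% and 4.30% in the mutant. Of 13 basement membrane genes, 11 rose, 1 fell and 1 did not pass, and 12 rose when adjusted over the list alone. Their median was 0.37, or 0.21 under the somatic centring, which includes them (camera adjusted p = 3.4e-10; adjusted p = 0.217 with an estimated correlation). The type IV collagen genes let-2 and emb-9 rose by 0.87 and 0.85, from 968 ± 97.9 to 1766 ± 126 and from 632 ± 49.4 to 1139 ± 70.3 CPM. The laminin gene lam-1 rose by 0.70 (SE 0.037, edgeR adjusted p = 9.36e-27), whereas the perlecan gene unc-52 had a log2 fold change of 0.11 that did not pass (edgeR adjusted p = 0.117). The faller, chosen after its value was seen, was the peroxidasin gene pxn-2.

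Lists of the other tissues moved less. Of 47 intestinal genes, 22 rose, 6 fell and 19 did not pass the test (24 and 6 when adjusted over the list alone), with a median of 0.15 that became -0.01 under somatic centring. The intestinal, cuticle collagen and neuronal lists are themselves among the somatic genes, so their medians near 0 after centring follow in part from its construction. The intestinal list was called higher (camera adjusted p = 8.43e-05; adjusted p = 0.319 with an estimated correlation). The intermediate filament gene ifc-1 and the filament organizer gene ifo-1 rose by 0.82 and 0.93, from 28.5 ± 0.31 to 50.2 ± 1.2 and from 23.6 ± 0.41 to 45.04 ± 3.05 CPM, and the abundant protease genes asp-1 and asp-3 by 0.21 and 0.19. Without mutant replicate 1 or 2, asp-1 kept log2 fold changes of 0.21 and 0.21 but did not pass (edgeR adjusted p = 0.0513 and 0.0665), as did asp-3 at 0.16 without mutant replicate 2 (0.129). Of 6 yolk protein genes, 5 rose and 1 fell, and the same numbers passed when adjusted over the list alone. Their median was 0.18, or 0.022 under somatic centring, and the list was marginal (camera adjusted p = 0.0495; adjusted p = 0.537 with an estimated correlation). vit-2 and vit-6 rose by 0.23 and 0.19, and vit-3 fell by 0.33. Some yolk genes are near-identical, which makes their counts uncertain, and which of these counts that affects was not examined. At similar log2 fold changes, vit-2 did not pass without mutant replicate 1 (0.23, edgeR adjusted p = 0.0613), nor vit-6 without mutant replicate 1 (0.18, adjusted p = 0.196) or 2 (0.20, adjusted p = 0.132). The yolk list was not called without N2 replicate 2 (camera adjusted p = 0.339), without mutant replicate 1 (0.241) or without mutant replicate 2 (0.311). Of 133 cuticle collagen genes, 38 rose, 12 fell and 83 did not pass, with 41 and 13 when adjusted over the list alone, and a median of 0.11 that became -0.05 under somatic centring. The list was called higher (camera adjusted p = 0.00947; adjusted p = 0.438 with an estimated correlation), but not without N2 replicate 1 (0.348) or mutant replicate 1 (0.0852). col-95 fell from 63.1 ± 2.41 to 31.02 ± 1.69 CPM, col-118 rose by 0.43, and the abundant genes col-140 and col-20 had log2 fold changes of 0.10 and 0.07 that did not pass the test (col-140 passed without N2 replicate 2, at 0.16 with an edgeR adjusted p of 0.00587). Taken alone, the 115 col genes, 27 higher and 12 lower, were not called as a name family (camera adjusted p = 0.225 over 173 families). Members under other names, chosen after their values were seen, included rol-6 (0.735), sqt-1 (0.629), sqt-2 (0.732) and sqt-3 (0.525), which rose. dpy-3 (0.106) did not pass. Of 71 neuronal genes, 8 rose, 6 fell and 57 did not pass, with 5 and 5 when adjusted over the list alone. Their median of 0.11 became -0.05 under somatic centring, and the list was not called (camera adjusted p = 0.382; adjusted p = 0.641 with an estimated correlation). The proprotein convertase gene egl-3 fell by 0.49 and the neuropeptide gene flp-13 rose by 0.58, with edgeR adjusted p values of 8.12e-11 and 1.51e-04.

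**Figure D3:**
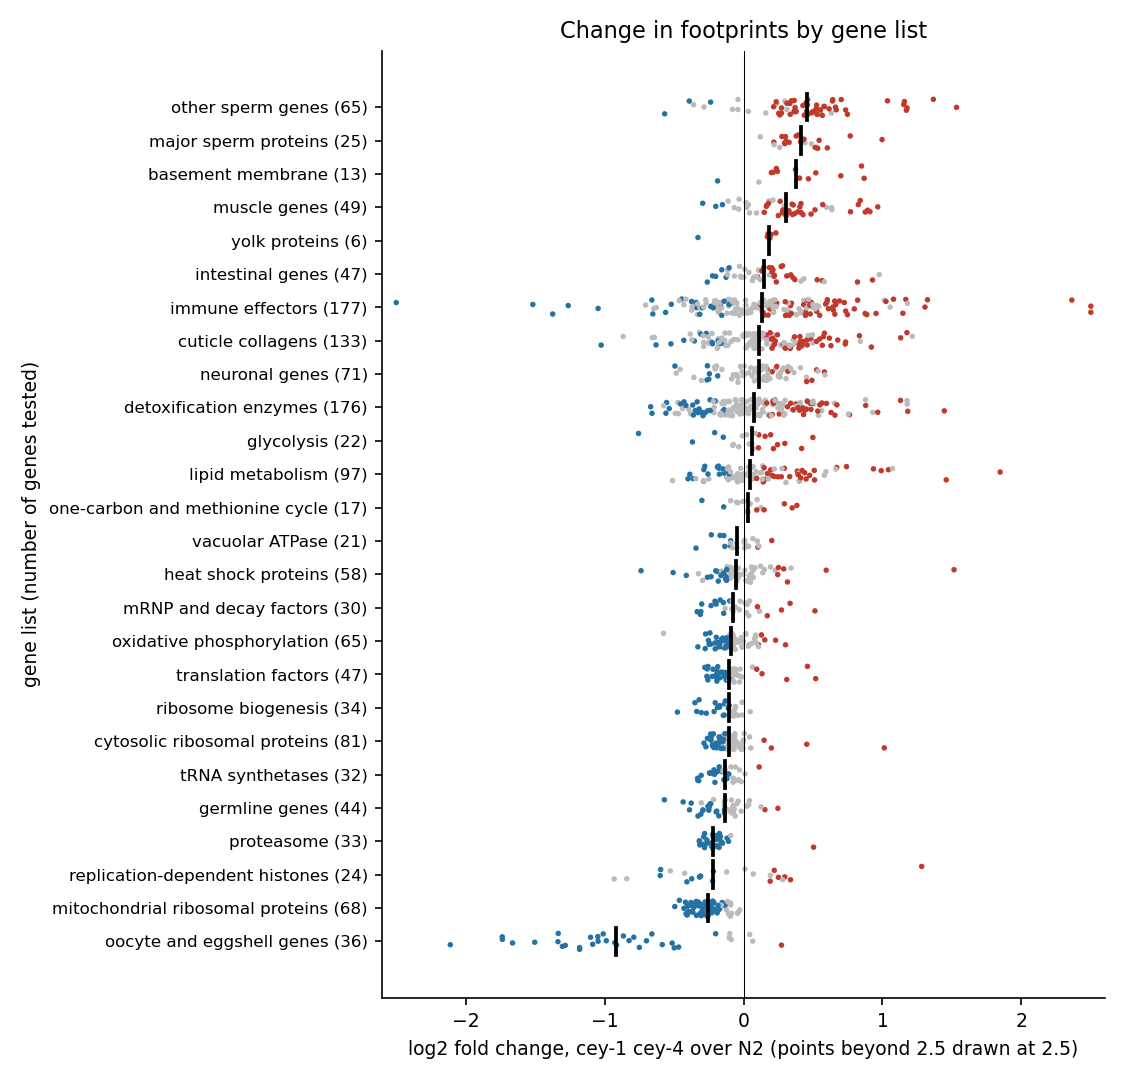
Log2 fold change (mutant relative to N2) of each tested member of 26 gene lists, 1 point per gene, with the list median as a black bar, genes past the edgeR test in red or blue and values beyond 2.5 drawn at that limit. The oocyte and eggshell list has the lowest median, -0.92, and the 2 sperm lists, the basement membrane and the muscle lists have medians of 0.31 to 0.45.

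Most genes of the mitochondrial ribosome and of the proteasome fell, by small amounts. Of 68 mitochondrial ribosomal protein genes, 55 fell, none rose and 13 did not pass the test, and 55 fell when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 7.47e-18; adjusted p = 0.189 with an estimated correlation). mrps-22 fell from 115 ± 0.65 to 86.6 ± 1.1 CPM (log2 fold change -0.41, SE 0.043, edgeR adjusted p = 1.68e-12) and mrpl-35 by 0.46, whereas mrpl-44 had a log2 fold change of -0.04 that did not pass. Of 33 proteasome genes, 31 fell, 1 rose and 1 did not pass, with 32 falling when adjusted over the list alone and a median of -0.22 (camera adjusted p = 1.11e-14; adjusted p = 0.189 with an estimated correlation). pas-1, a subunit of the core particle, fell by 0.32 and rpn-3, a subunit of the regulatory particle, by 0.32, each with SE 0.037. rpn-1 did not pass (log2 fold change -0.09, edgeR adjusted p = 0.0787), and the member that rose, rpn-6.2, was chosen after its value was seen.

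The lists of cytosolic ribosomal proteins, translation factors, tRNA synthetases and ribosome biogenesis were called slightly lower, although many of their members did not pass the test and some rose. The medians of these lists were no larger in size than that of the germline list (-0.137). Whether these lists moved apart from the germline genes was not tested. Of 81 cytosolic ribosomal protein genes, 25 fell, 4 rose and 52 did not pass the test, 26 fell when adjusted over the list alone, and the median was -0.11. That median became -0.06 with upper-quartile factors and -0.267 under somatic centring. The list was called lower (camera adjusted p = 3.18e-09; adjusted p = 0.438 with an estimated correlation). rpl-28 and rpl-5 fell by 0.26 and 0.19 (without mutant replicate 1 or 2, rpl-5 stayed at -0.19 and -0.20 with edgeR adjusted p of 0.0934 and 0.0695), rack-1 had a log2 fold change of 0.00, and rpl-11.2 rose from 719 ± 28.2 to 986 ± 62.2 CPM (log2 fold change 0.45, SE 0.051, edgeR adjusted p = 2.18e-11). The other risers, chosen after their values were seen, were rpl-42, rpl-25.1 and rps-28. rpl-42 had a mean of only 1.40 CPM, against a list median of 1430 CPM. rpl-11.1, also chosen afterwards, fell by 0.18 (edgeR adjusted p = 0.0106), whereas its paralog rpl-11.2 rose. Of 47 translation factor genes, 21 fell, 5 rose and 21 did not pass, 22 fell when adjusted over the list alone, and the median was -0.11 (camera adjusted p = 1.02e-04; adjusted p = 0.238 with an estimated correlation). That median became -0.059 with upper-quartile factors and -0.265 under somatic centring. The elongation factor genes eef-1A.1 and eef-1A.2 moved apart: eef-1A.1 fell by 0.16 (SE 0.051, edgeR adjusted p = 0.00915; -0.14 and -0.19 with adjusted p of 0.31 and 0.142 without mutant replicate 1 or 2) and eef-1A.2 rose by 0.46 (SE 0.052, edgeR adjusted p = 1.39e-11). The poly(A)-binding protein gene pab-2 rose by 0.52 (SE 0.043, edgeR adjusted p = 4.25e-17), and the other risers, chosen after their values were seen, were eif-4A3, ifg-1 and iff-2. Of 32 tRNA synthetase genes, 18 fell, 1 rose and 13 did not pass, 19 fell when adjusted over the list alone, and the median was -0.14 (camera adjusted p = 3.6e-06; adjusted p = 0.189 with an estimated correlation). That median became -0.091 with upper-quartile factors and -0.297 under somatic centring. gars-1 fell by 0.33, kars-1 by 0.24 and mars-1 by 0.23, and wars-1, the riser, was chosen after its value was seen. Of 34 ribosome biogenesis genes, 17 fell, none rose and 17 did not pass, 17 fell when adjusted over the list alone, and the median was -0.11 (camera adjusted p = 7.14e-06; adjusted p = 0.238 with an estimated correlation). That median became -0.06 with upper-quartile factors and -0.266 under somatic centring. The nucleolar genes dao-5, nol-58 and fib-1, which encodes fibrillarin, fell by 0.48, 0.32 and 0.14, though fib-1 did not pass without N2 replicate 2 or mutant replicate 1 (-0.10 and -0.07, edgeR adjusted p = 0.146 and 0.467). Of 30 genes for mRNP and decay factors, 12 fell, 5 rose and 13 did not pass, 13 fell when adjusted over the list alone, and the list was not called (median -0.08, camera adjusted p = 0.0546; adjusted p = 0.364 with an estimated correlation). The helicase gene cgh-1 and its partner car-1, both abundant in germline mRNPs, fell by 0.33 and 0.20 (car-1 stayed at -0.19 with an edgeR adjusted p of 0.0509 without mutant replicate 1), edc-3 fell by 0.30 and ain-1, a component of the microRNA effector complex, rose by 0.51.

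Oxidative phosphorylation genes fell slightly as a list: of 65, 31 fell, 5 rose and 29 did not pass the test, 36 fell when adjusted over the list alone, and the median was -0.09. camera called the list lower (adjusted p = 2.28e-04; adjusted p = 0.438 with an estimated correlation), but not without N2 replicate 2 (0.0821). The germline-enriched ATP synthase gene asb-1 fell by 0.33 and the complex I gene gas-1 rose by 0.30, with edgeR adjusted p values of 6.92e-12 and 4.75e-10. atp-1 and atp-2 had log2 fold changes of 0.11 and 0.09 that did not pass. The other risers, nuo-5, ucr-2.1, cox-6C and sdha-1, were chosen after their values were seen. Of 21 vacuolar ATPase genes, 7 fell, 2 rose and 12 did not pass, with 7 and 2 when adjusted over the list alone, and the list was not called (median -0.05, camera adjusted p = 0.288; adjusted p = 0.438 with an estimated correlation). vha-9 fell by 0.23 and the intestinal subunit gene vha-6 rose by 0.20. Of 58 heat shock protein genes, 15 fell, 6 rose and 37 did not pass, with 15 and 7 when adjusted over the list alone, and the list was not called (median -0.06, camera adjusted p = 0.0546; adjusted p = 0.238 with an estimated correlation). The small heat shock protein gene sip-1 fell from 947 ± 11.3 to 568 ± 13.7 CPM (log2 fold change -0.74, SE 0.048, edgeR adjusted p = 5.12e-22), the Hsp70 gene hsp-1 fell by 0.19 (-0.18 and -0.20, with adjusted p of 0.123 and 0.0742, without mutant replicate 1 or 2), hsp-17 rose by 0.59 and hsp-90 did not pass, at -0.05.

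More immune effector genes rose than fell, though their median turned negative under somatic centring, and none of the 4 metabolic lists after them was called. Of 177 immune effector genes, 53 rose, 21 fell and 103 did not pass the test, with 54 and 22 when adjusted over the list alone. Their median of 0.13 became -0.03 under somatic centring (camera adjusted p = 0.0111; adjusted p = 0.189 with an estimated correlation). dod-23 rose from 74.1 ± 1.62 to 183 ± 5.27 CPM (log2 fold change 1.31, SE 0.042, edgeR adjusted p = 6.73e-40), the lysozyme gene lys-2 rose by 0.87, the C-type lectin gene clec-63 by 0.34, and the invertebrate lysozyme gene ilys-5 fell by 0.52. Of 176 detoxification genes, 36 rose, 25 fell and 115 did not pass, with the same numbers when adjusted over the list alone. The median of 0.07 became -0.09 under somatic centring and the list was not called (camera adjusted p = 0.382; adjusted p = 0.624 with an estimated correlation). dhs-26 rose by 0.97 (SE 0.052, edgeR adjusted p = 5.12e-26) and the glutathione S-transferase genes gst-7 and gst-1 fell by 0.55 and 0.24. Of 97 lipid metabolism genes, 29 rose, 16 fell and 52 did not pass, with 34 and 20 when adjusted over the list alone, a median of 0.05 that became -0.11 under somatic centring, and no call (camera adjusted p = 0.0878; adjusted p = 0.555 with an estimated correlation). The palmitoyl-CoA desaturase gene fat-5 rose by 0.94, from 53.5 ± 1.59 to 102 ± 2.16 CPM, the peroxisomal oxidase gene acox-1.5 by 0.74 and the fatty acid synthase gene fasn-1 by 0.45. The acyl-CoA dehydrogenase gene acdh-1 fell by 0.18 (edgeR adjusted p = 0.00716; -0.13 with 0.0618 without N2 replicate 1 and -0.17 with 0.0775 without mutant replicate 2). Of 22 glycolysis genes, 9 rose, 4 fell and 9 did not pass, with 10 and 4 when adjusted over the list alone, a median of 0.06 that became -0.10 under somatic centring, and no call (camera adjusted p = 0.199; adjusted p = 0.624 with an estimated correlation). The hexokinase gene hxk-1 fell from 40.1 ± 0.39 to 23.8 ± 0.078 CPM and pck-1, which encodes phosphoenolpyruvate carboxykinase, rose by 0.42. Of 17 one-carbon and methionine cycle genes, 5 rose, 2 fell and 10 did not pass, with 7 and 2 when adjusted over the list alone, a median of 0.03 that became -0.13 under somatic centring, and no call (camera adjusted p = 0.132; adjusted p = 0.364 with an estimated correlation). The adenosylhomocysteinase gene ahcy-1 rose by 0.35 and the cystathionine gamma-lyase gene cth-1 by 0.38.

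The values are shares of footprints within a library, so they depend on the scaling: higher genes made up 51.1% of the calls, 63.1% with upper-quartile factors (2730 higher, 1598 lower) and 20.5% when libraries were centred on 313 somatic genes (1197 higher, 4653 lower), which lowered each list median by 0.16 on the log2 scale and was chosen after the data were seen. The labels do not say that replicates came from separate cultures, so p values measure the spread between these libraries, which may be technical; DESeq2's test called 1007 genes higher and 1171 lower.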

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

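Centring on the somatic lists was chosen only after the result was seen; the other alternatives were planned. Leaving out 1 library at a time gave 1624 to 1963 higher and 1540 to 1922 lower genes, and DESeq2's Wald test gave 1007 and 1171, with 1523 adjusted p values undefined. The test against a fold change of 1.2 gave 809 and 450, and somatic centring 1197 and 4653, where by construction every fold change fell by 0.16; glh-1 became -0.12, pck-2 -0.14 and pmt-2 -0.012. The replicate block gave 2431 and 2351. Deviations of same-numbered libraries correlated at 0.087 over all genes and 0.267 over genes of 100 or more counts, in the direction that pairing would give. The labels do not say that the numbers pair the libraries, so whether they do is not known. With at least 50 counts, the mean Spearman correlation was 0.9963 within groups and 0.9835 between them, over fewer genes. Lists whose camera adjusted p crossed the threshold were, with DESeq2's size factors, mRNP factors (0.048), yolk (0.0506) and heat shock (0.0451); with upper-quartile factors, lipid (0.0349) and one-carbon genes (0.0394); without a low-count filter, mRNP factors (0.022) and heat shock (0.0146); with at least 50 counts, yolk (0.0824); with the deposited log2 values, yolk (0.242) and collagens (0.0589); and with the replicate block, heat shock (0.0442). fry gave 0.141 for ribosomal proteins and for oxidative phosphorylation, 0.307 for yolk, 0.166 for collagens, 0.0367 for mRNP factors, 0.0293 for heat shock and 0.0191 for one-carbon genes. With an estimated correlation camera called 0 of 27 lists, 6 had an unadjusted p under 0.05, and fry called 17. The estimated-correlation adjusted p was 0.189 for mitochondrial ribosomal proteins, tRNA synthetases, oocyte, germline, both sperm, muscle, immune and proteasome lists, 0.208 Y-box, 0.217 basement membrane, 0.238 translation factors and ribosome biogenesis, 0.319 intestine, 0.438 ribosomal proteins, collagens and oxidative phosphorylation, and 0.537 yolk. Without 1 library each, yolk ranged from 3.3e-07 to 0.339, collagens from 0.00167 to 0.348, lipid genes from 0.017 to 0.327 and oxidative phosphorylation from 2.21e-04 to 0.0821. Each of these fits has 1 residual degree of freedom, so a call can end with its fold kept. Against random lists matched on abundance, the called yolk list had a median well inside the range (percentile 77.73). The called lists of ribosome biogenesis and oxidative phosphorylation lay near its lower edge (5.63 and 5.47), while uncalled lists lay at 99.62 (lipid), 98.92 (glycolysis), 97.8 (detoxification) and 0.04 (histones). The cause of the other differences was not tested. Of the 125 named genes, 124 kept their side of the threshold with DESeq2's size factors, 122 with its Wald test and 114 without mutant replicate 2, the setting with the fewest besides somatic centring (108) and the fold test (87). No alternative for coding length was run, since no coding lengths were given.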

Other observations

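Most tests in this part were chosen only after the results were seen. The exceptions are the edgeR test of single genes, the list tests of the yolk genes, the test of the genes 7 to 20 places from cey-4 and that of the other splits of the libraries. Setting the yolk genes against an earlier harvest was chosen afterwards. The genes named here were chosen after their values were seen. Among 173 gene-name families of at least 8 members, camera at the preset correlation called 30, including the mcm and npp families as lower. With an estimated correlation camera called no family, the lowest adjusted p being 0.751. Of 8 genes with the mcm prefix, 6 fell, mcm-2 to mcm-7, which encode the replicative helicase (median log2 fold change -0.54, camera adjusted p = 1.98e-07; adjusted p = 0.751 with an estimated correlation). mcm-3 fell from 160 ± 0.93 to 90.2 ± 1.07 CPM (log2 fold change -0.83) and mcm-5 by 0.72. Of 25 nuclear pore (npp) genes, 17 fell and none rose (median -0.15, camera adjusted p = 1.06e-05; adjusted p = 0.751 with an estimated correlation), with npp-12 at -0.24. Of 20 neprilysin-family (nep) genes, 12 rose and none fell (median 0.41, camera adjusted p = 0.00155; adjusted p = 0.751 with an estimated correlation); nep-23 rose from 6.05 ± 0.18 to 12.9 ± 1.45 CPM. Of the C-type lectin (clec) genes, 39 rose, 8 fell and 57 did not pass the test (median 0.23, camera adjusted p = 5.23e-04; adjusted p = 0.751 with an estimated correlation). Both of these medians exceed the 0.16 shift of the somatic centring. The P granule genes meg-2 and meg-4 fell by 1.56 and 1.57, beside meg-1 and meg-3.

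K08E7.6 took 1.54% and 0.284% of counts in the N2 libraries and 0.361% and 0.00113% in the mutant ones, a 317-fold spread between the mutant libraries. M163.7, at 13, 1.83, 3.30 and 0 CPM, and W07G1.1, at 15.2, 3.34, 3.67 and 0.045 CPM, had the same order of libraries. These were among 5 of 8636 genes with a mean of 100 or more counts that differed by more than 2-fold within a group. fipr-6 had 24 and 27 counts in N2 and none in either mutant library, at least 14-fold lower against a floor of 3 counts over both mutant libraries together. The giant muscle gene unc-89 had a log2 fold change of 0.64 that did not pass the edgeR test (adjusted p = 0.285), with 423 and 277 CPM in the N2 libraries.

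Oocyte and eggshell genes were lower and sperm genes higher in the mutant. A smaller share of the germline as a whole would lower its other genes alike, but the median of the germline list lay above that of the oocyte list by 0.783 on the log2 scale (95% interval 0.549 to 0.959, bootstrap over genes). That interval covers the spread among the listed genes, which may move together, and not the spread between libraries. The oocyte list was singled out for its low median, so a gap to another list was already known. The germline list itself fell (20 lower, 2 higher, median -0.137). A smaller germline share as part of the cause therefore stays open. Reads shared between near-identical copies would not raise the spe genes, which were taken to be distinct in sequence without examining it. Of 26 spe genes 65.4% rose (exact binomial 95% interval 44.3 to 82.8, with genes counted as independent), against 2278 of all 13086 genes tested. This argues against shared reads as the whole cause of the sperm rise, but the msp counts may still hold shared reads. An earlier harvest, with yolk genes then lower, stays open: the yolk median was 0.182, but only 0.022 when centred on somatic genes, and the yolk list's call was marginal (camera adjusted p = 0.0495; 3.3e-07 to 0.339 over leave-one-out fits with 1 residual degree of freedom each, and 0.537 with an estimated correlation). Only the yolk genes were set against an earlier harvest. Genes such as fog-3, which promotes the sperm fate and rose, and the cuticle collagen genes were not weighed for it. An effect of the genotype also stays open and was not tested.

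Higher muscle and basement membrane genes could arise arithmetically, since fewer oocyte footprints raise the share of every somatic message. That explanation predicts like gains in all somatic lists. The muscle median exceeded the neuronal one by 0.198 (95% interval 0.105 to 0.287, from a bootstrap over genes that leaves out the spread between libraries). This argues against like gains for the muscle and neuronal lists only. Neuronal genes were of lower abundance, with a median of 4.22 CPM against 314 CPM for muscle, and basement membrane genes were not compared. A trend of fold change with abundance is argued against too, since the muscle median lay above 100% of 10000 random lists matched on mean CPM. The muscle list was singled out for its high median, however, and random lists leave out genes that move together. An effect of the genotype on these messages stays open and was not tested.

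Genes beside cey-4 included several that passed the test: of 9 tested within 6 places, 5 passed the edgeR test, oxi-1 (-1.29), pde-12 (-0.99), hex-3 (-0.60), sbsp-1 (0.48) and C44B9.2 (1.40), and their window's median absolute log2 fold change of 0.603 lay at percentile 98.66 of 12462 windows, against 31.86 around cey-1. A linked sequence difference carried along with the cey-4 allele cannot be told apart from chance: 30.4% of the genes 7 to 20 places away passed (exact binomial 95% interval 13.2 to 52.9), against 34.5% of all genes. Reads of cey-4 counted in its neighbour oxi-1 would leave the other neighbours unmoved, and 4 of them passed the test; but with 5 of 9 the window lies at percentile 86.36 of windows by share passing, so this too stays open. oxi-1 lost 1.93% of the CPM that cey-4 lost. Of the 3 splits of the 4 libraries into 2 and 2, 1 gave as many calls as the real one, the real split itself with 4455, and the highest of the others gave 0 with edgeR and with limma-voom (64 and 48 genes at an unadjusted p under 0.05); so few splits cannot give a share under 0.05.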
